A study of Rattus norvegicus with 2 samples.

How the data were processed

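Total RNA came from the nucleus of the solitary tract (NTS), a centre of the dorsal medulla that receives cardiovascular and visceral input, of male and female spontaneously hypertensive rats (SHR), a strain that develops high blood pressure. Per the labels' protocols the rats were 9 weeks old, 1 operator took all tissue under a dissecting microscope, and equal amounts of RNA from 5 rats of a sex, 100 ng each, were pooled. Per the labels, 100 ng of each pool was amplified, labelled with Cy3 and hybridised to a 1-colour Agilent rat array, so the design has 2 arrays, 1 per sex. Each group was taken from the sex given in the labels. Both arrays were on 1 slide and were read in 1 scan, so slide and scan do not separate the sexes.

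The deposited scanner values are spot intensities on a linear scale, written by Agilent Feature Extraction, whose processed signal is already background-corrected. The submitters' processing notes name version 9.1 of that program and the file headers name version 11.5.1.1. The authors' deposited value table lists 48346 spots, all of them outside the control spots and without outlier flags. Each of its columns equalled that array's processed intensity divided by 1 constant, 22.8 on the male and 23.4 on the female array, with an SD of the log2 ratio of 0.00046 and 0.00034. That division places the 75th percentile of an array at 100, so the table is linear, is not centred by gene, and has no direction of its own. Its column medians were 19.4 for the male and 19.6 for the female array.

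Each array had 58717 spots outside the controls. Of these, 80.1% were well above background on the male array and 82.3% on the female array. The 75th percentile of the processed signal was 1169 times the median of the negative control spots on the male array and 1238 times on the female array. No spot was saturated. The main setting took log2 of the processed signal minus each array's 75th percentile. Control spots were left out, as were spots carrying an outlier flag on either array (284 were flagged on the male and 363 on the female array). Repeated spots of a probe were averaged on the log2 scale. A probe was measured when it was well above background on both arrays, and a gene's value was the mean over its measured probes. Signals in the text are on a scale where the 75th percentile of each array is 100, called scaled signal. Differences are female minus male, and a fold is the brighter over the dimmer array.

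The files give transcript accessions but no gene symbols. Of 45595 probes, 21109 were named by matching accessions, without versions, to a RefSeq gene table of assembly GRCr8, which gave 16581 genes. No match was made for the 6958 probes with Ensembl transcript identifiers, and 24486 probes stayed without a name. The array design in the headers uses an older rat assembly, so that table served for names only and no coordinates are given.

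With 1 array per sex there is no estimate of the variation between animals or pools, and no test or p-value is given. Genes were counted past a fixed 2-fold difference. A gene with all probes below background on 1 array has only a bound there: its brightest probe was set against the higher of its own dim signal and the lowest signal among probes well above background on that array, written as "at least". The technical error was read from probes with at least 8 spots measured on both arrays. Gene lists were fixed before the data were examined, and 35 of 36 had at least 4 measured genes. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these 2 arrays. The numbers come from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and from R 4.3.3 with limma 3.58.1.

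Named genes followed a rule also fixed before the data were examined. It takes the Y-linked genes, and the 12 genes with the highest and the 12 with the lowest difference among measured genes with a plain symbol, a mean signal above the 25th percentile and all probes in the same direction. It adds the 5 plain-symbol genes with the largest bound in each direction, and from each list up to 4 members past 1.5-fold, or the 2 brightest where none was. Some genes that the rule picked are not reported here. Alternatives were normexp background correction with an offset of 50, no background correction, quantile, median and loess scaling, the authors' table, other filters on dim probes, other summaries of a gene, outlier-flagged spots kept, and folds of 1.5 and 3. The normexp and uncorrected settings used each spot's median signal where the plan had named its mean. Centring on spike-in controls, counts without the choroid plexus and blood lists, 3 further marker lists and the place of each outlying list among random lists drawn under every other setting were added after the first results were seen. On simulated arrays with the median spot noise of each signal quartile, all 100 genes given a 3-fold difference passed 2-fold, and none of 13228 unaltered genes did. With the 95th percentile of that noise, 98 of the 100 passed, and so did 8 unaltered genes, all among the 3312 in the dimmest 25%. In the same simulation 219 of those 3312 passed 1.5-fold. These simulations, also run after the results were seen, cover spot noise alone. Of 200 simulated lists of 20 unaltered genes, 7.5% lay outside the 95% range at the median noise and 5.5% at the higher noise. The noise was independent between genes, so these rates do not cover lists whose members vary together.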

Results

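Gene expression was measured in the NTS of 9-week-old SHR of both sexes, to compare males with females in a brainstem centre of blood pressure control. Each sex was represented by 1 array of RNA pooled from 5 rats. There were no replicate arrays, so every difference below compares 2 pools, and its variation between animals is unknown. Of 16581 named genes on the array, 13428 were well above background on both arrays.

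The sex labels were checked first with Y-linked genes. Eif2s3y, a Y-linked translation initiation factor gene, had a scaled signal of 22.4 on the male array and was not well above background on the female array, at least 65.0-fold lower. Ddx3y, a Y-linked RNA helicase gene, had 2 probes that differed in size. The first gave 6.94 on the male array and was not well above background on the female array, at least 20.2-fold lower, and the second gave 24.3 against 10.2, a 2.40-fold difference. Tspy1 had 1 probe above background, at 2.35 on the male and 2.57 on the female array, and its other probe and the probes of Uty and Ube1y1 were below background on both. Of the X-linked partners, Eif2s3 was 1.41-fold higher on the female array, with both of its probes in that direction, and Uba1 was within 1.02-fold. The median of the 4 measured X-linked partners was 0.12 on the log2 scale. Xist, also on that list, had no named probe.

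Between the sexes, 54 genes were at least 2-fold higher on the female array and 20 were at least 2-fold higher on the male array. Leaving out the dimmest 25% of genes with a plain symbol, the 2 largest differences on the female side were in genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid. Sostdc1, a secreted antagonist of BMP and Wnt signals, was 18.8-fold higher. Ttr, the thyroxine carrier of cerebrospinal fluid, reached 9325 on the female array against 617 on the male array, a 15.1-fold difference. On the male side, with the same limit, the difference was largest for Adamts19, a secreted metalloprotease gene, at 5.54-fold, followed by the inducible heat shock gene Hspa1a at 3.71-fold and Ctsk, the protease cathepsin K, at 3.35-fold.

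Of the other genes named on the female side, Otx2, Kcne2, Enpp2, Aqp1, Igfbp2 and Folr1 are also on the choroid plexus list. The transcription factor gene Otx2 was 6.78-fold higher and the osmosensitive channel gene Trpv4 was 5.18-fold higher. S100g, a calcium-binding protein gene, was 4.19-fold higher, the potassium channel subunit gene Kcne2 2.47-fold and Enpp2, which makes lysophosphatidic acid, 2.39-fold. The water channel gene Aqp1 was 2.26-fold higher, the antiviral gene Rsad2 2.15-fold, Igfbp2 2.09-fold, the folate receptor gene Folr1 1.95-fold and Sfrp2 1.93-fold. The 2 probes of Aqp1 differed in size, at 0.61 and 1.75 on the log2 scale, as did those of Kcne2, at 0.63 and 1.98. On the male side, Calca, which encodes calcitonin gene-related peptide, was 2.48-fold higher and Olfml3 2.39-fold higher. Uts2, the gene of the vasoactive peptide urotensin 2, was 2.37-fold higher, Wfdc1 2.09-fold, Spp1, which encodes osteopontin, 2.07-fold and Thbs4 1.98-fold. Cdc14a was 1.98-fold higher as a mean of probes at -1.82 and -0.14, and the haemoglobin chaperone gene Ahsp was 1.89-fold higher.

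**Figure D1:**
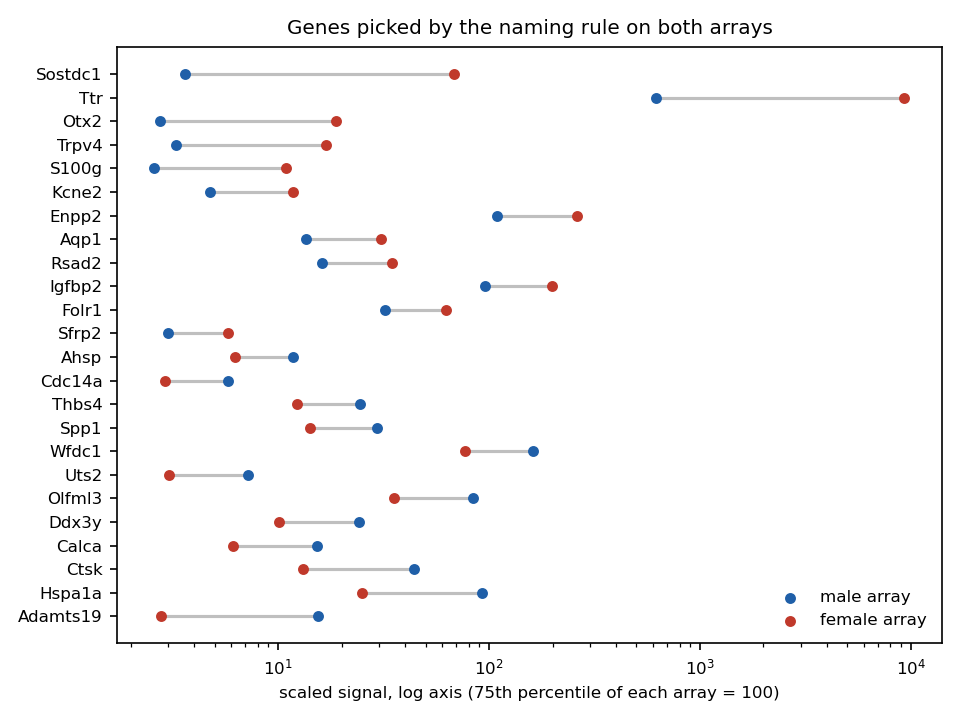
Scaled signal (log axis, 75th percentile of each array = 100) of the 12 genes with the highest and the 12 with the lowest difference among those with a plain symbol, a mean signal above the 25th percentile and all probes in the same direction, with 1 point per array joined by a line. Ttr reached 9325 on the female array against 617 on the male array, and Hspa1a 93.0 on the male array against 25.1 on the female array.

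The arrays were alike for most genes: 13120 of 13428 genes lay within 1.5-fold, and the SD of the differences over genes was 0.23 on the log2 scale. That SD over genes was 0.36 in the dimmest and 0.13 in the brightest 25% of the signal range. Over 1323 probes with repeated spots, 1126 of them in that brightest 25%, the median SD of the difference between arrays was 0.04. This spot SD covers spots but not animals, pools, labelling or arrays. It was 0.18 in the dimmest 25% of the signal range, which held 53 of the genes past 2-fold. Of 3050 genes with several measured probes, 30 were past 1.5-fold, and 29 of these had all probes in the same direction. The mean of the same probes picked these genes, which favours such agreement. Normexp correction of each spot's median signal gave 20 genes 2-fold higher on the female and 7 on the male array, and the same signal without background correction gave 22 and 9. Of the genes named here, Cdc14a, Mas1, Ucn, Lepr, Npr3, Sstr2, Oxtr, Cxcl9, Ccl21, S100a8, S100a9, Ciita, RT1-Da, RT1-Db2, Ifit3, Fat2, Slc47a1, Slc4a1, Alas2, Ccn1, Fos, Zbtb16, Scn10a and Rpl39l1 were past 1.5-fold in the main setting but not with normexp. The split of 54 to 20 was 7 to 8 in the brighter part of the probes, 43 to 31 after quantile normalization and 70 to 13 after centring on spike-in controls, a setting chosen after seeing the data.

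**Figure D2:**
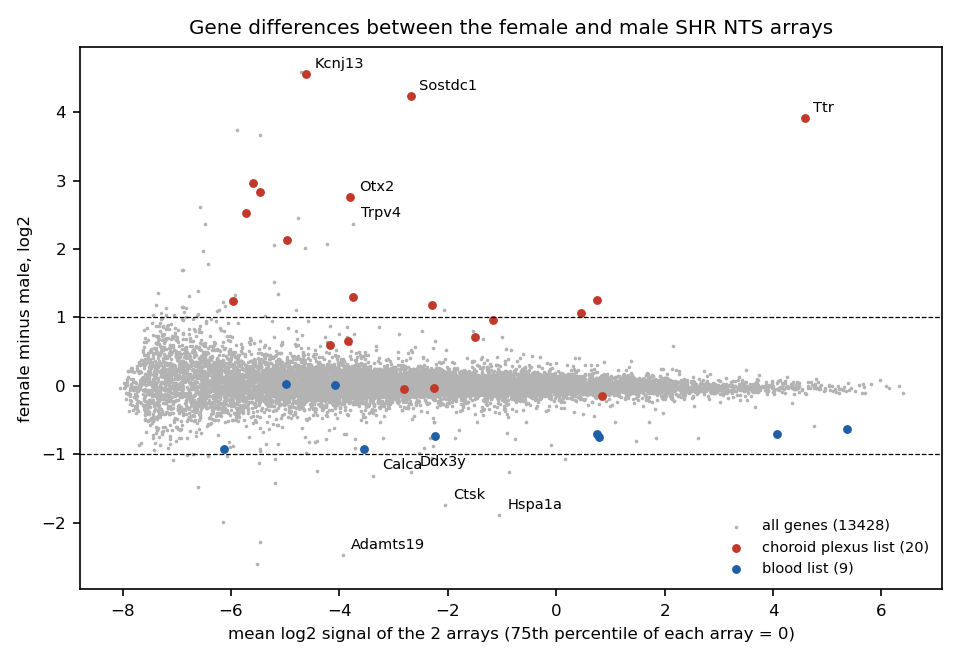
Female minus male difference (log2) against the mean log2 signal of the 2 arrays (75th percentile of each array = 0) for 13428 genes, with the 20 measured choroid plexus genes in red, the 9 blood genes in blue and dashed lines at 2-fold. Choroid plexus genes lie above the upper line in 13 cases, and no blood gene is past 2-fold.

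The choroid plexus list stood furthest from the other lists. Of its 20 measured genes, 17 were at least 1.5-fold higher on the female array and none was on the male array. The median was 1.25 on the log2 scale, against -0.04 to 0.09 for the middle 95% of matched random lists. The potassium channel gene Kcnj13 was 23.5-fold higher and the prolactin receptor gene Prlr 7.79-fold higher. Both were dim on the male array, with scaled signals of 0.84 for Kcnj13 and 0.74 for Prlr. Over the other settings, Kcnj13 fell from 4.56 to as low as 2.499 on the log2 scale, and Prlr from 2.96 to 1.13. Of the 54 genes past 2-fold, 13 belonged to the choroid plexus list. Markers of meninges and connective tissue had a median of 0.16 (random lists -0.03 to 0.06), and Igfbp2 is on both lists. The median was 0.084 with normexp and 0.094 after quantile normalization, both above their random lists, and 0.048 in the brighter part of the probes, inside the range. Slc47a1, an organic cation exporter gene, was 2.25-fold higher on the female array and Igf2 1.74-fold higher, while the collagen gene Col1a2 was 1.70-fold higher on the male array. The ependymal list (median 0.07) and the cerebellar list (0.09) lay inside their random ranges. Their named members were Tppp3, within 1.08-fold, Cd24, 1.22-fold higher on the male array, and the dim gene Fat2, 2.05-fold higher on the female array.

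In the renin-angiotensin list (median 0.03, inside the random range), 3 of 13 measured genes were past 1.5-fold, in both directions. The share over all genes was 2.29%, which is not matched on signal. Mme, which encodes the peptidase neprilysin, was dim, at 1.59 on the male and 4.56 on the female array, a 2.87-fold difference that was 1.52 on the log2 scale and 0.72 with normexp. Ace, the angiotensin-converting enzyme gene, was 1.70-fold higher on the female array, and Mas1, the receptor gene for angiotensin-(1-7), was 1.63-fold higher on the male array. Among neuropeptide receptors (0.03) the leptin receptor gene Lepr was 2.16-fold and the natriuretic peptide clearance receptor gene Npr3 1.78-fold higher on the female array. Sstr2 was 1.55-fold and the oxytocin receptor gene Oxtr 1.54-fold higher on the male array. The sex steroid and corticosteroid list (0.02) had only Prlr past 1.5-fold, and Prlr also belongs to the choroid plexus list. The female array on which Mme, Ace, Lepr, Npr3 and Prlr were higher was also the array with the choroid plexus median of 1.25. The noradrenaline synthesis genes Th and Dbh were within 1.13-fold and 1.05-fold, and the catecholamine list had a median of 0.01. In the nitric oxide and oxidative stress list (-0.01), Sod1 and Gpx4 were within 1.02-fold.

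Neuronal and glial lists differed little in size, and several stood lower on the female array. The oligodendrocyte list had a median of -0.17 with 25 of 27 genes higher on the male array, and Qdpr was 1.15-fold higher there. The serotonin and acetylcholine list had a median of -0.15 with 13 of 20 genes higher on the male array. The choline transporter gene Slc5a7 was 1.17-fold and Ache 1.09-fold higher there, and the serotonin synthesis gene Tph2, chosen after the values were seen, was 1.34-fold higher on the female array. The median of the vagal and hypoglossal motor neuron list was -0.14, and Calca was its 1 member past 1.5-fold. Chat, Slc18a3 and Slc5a7 are on both of these lists. Neuron markers had a median of -0.04, with Uchl1 and Gap43 within 1.03-fold, and endothelial and mural markers -0.07, with Bsg within 1.01-fold and Slc2a1 within 1.04-fold. These 5 lists were below the middle 95% of their random lists. The neuron list was at the edge of its range and inside it in 5 of 13 other settings, whereas the other 4 stayed below in all 13. Median and spike-in centring move all genes by a common step, the authors' values are the same signal, and no spot was saturated. Such settings can barely move a list's place and add little to these counts. The serotonin and acetylcholine median was -0.068 with normexp, -0.053 without background correction and -0.067 in the brighter part of the probes. That of the endothelial list was -0.039 with normexp, -0.035 without background correction and -0.11 after quantile normalization. Centring on spike-in controls adds the same step to every gene, so it turned the neuron median to 0.05 and the endothelial median to 0.02 while leaving each list below its random lists. Inside the random range were the glutamate list (0.03), with Slc1a3 within 1.07-fold and Slc17a6 within 1.09-fold, and the inhibitory transmitter list (0.00), with Gabbr1 and Glra2 within 1.02-fold. The neuropeptide list (0.00) was inside too, with Calca and Ucn, 1.93-fold higher on the male array, past 1.5-fold. So were astrocyte markers (0.00), with Aldoc within 1.02-fold and Apoe within 1.01-fold, ion channels (0.02), where the dim Scn10a was 1.61-fold higher on the female array, and growth factors (0.01), where Igf2 was past 1.5-fold. Hox genes (0.08) had Hoxb5 within 1.11-fold and Hoxb4 within 1.04-fold, and pituitary hormones (-0.02) had Pomc within 1.11-fold and Lhb within 1.02-fold.

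Of 9 measured blood genes, 7 were at least 1.5-fold higher on the male array, with a median of -0.71 against -0.07 to 0.10 for random lists. The dim anion exchanger gene Slc4a1 was 1.90-fold higher, the haem synthesis gene Alas2 1.66-fold and the globin gene Hbb 1.68-fold. The platelet genes Pf4 and Gp9, chosen after the values were seen, were within 1.00-fold and 1.02-fold. The granulocyte genes S100a8 and S100a9 were 1.89-fold and 1.81-fold higher on the male array, in a list with a median of -0.07 inside the random range. The immediate early list had a median of -0.09, below its random lists, with Ccn1 1.76-fold and Fos 1.53-fold higher on the male array. In the brighter part of the probes the median was -0.038, inside the range. The common step of centring on spike-in controls made it 0.0017, still below the random lists. Hspa1a and Hspb1, at 1.82-fold, were higher on the male array in a heat shock list with a median of -0.02.

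In the cytokine list (median -0.02, inside the random range) the chemokine gene Cxcl10 was 5.49-fold higher on the female array, Cxcl9 1.77-fold and Ccl21 1.63-fold. Cxcl9 and Ccl21 were dim, both at 0.53 on the male array, and both were within 1.03-fold with normexp. Over the other settings Cxcl10 fell from 2.46 to as low as 1.49 on the log2 scale. In the interferon list (0.06, inside) the dim Ifit3 was 2.52-fold and Rsad2 2.15-fold higher on the female array. The antigen presentation list lay below its random lists at -0.07, and also at 0.03 after the common step of centring on spike-in controls. Its members went in opposite directions, so the median does not describe them all. Ciita, RT1-Da and RT1-Db2 were 1.75-fold, 1.62-fold and 1.54-fold higher on the female array. The class II genes Cd74 (0.48) and RT1-Bb (0.43) were also higher there, but RT1-DMa was at -0.07. Class I genes such as RT1-A1 (-0.09), RT1-A2 (-0.16) and RT1-CE3 (-0.15) were lower there, but RT1-M3-1 was at 0.04. Microglial markers (-0.03) were inside the range, with Ctss within 1.01-fold. Glucocorticoid-responsive genes (0.09) lay above their random lists, with the dim Zbtb16 1.97-fold higher on the female array, at 1.70 against 0.86. Clock genes (0.09) lay just above theirs, with 13 of 15 genes higher on the female array, but inside the range in 5 of 13 other settings, at 0.035 with normexp. Of these, Cry2 was within 1.00-fold, Dbp was 1.10-fold higher on the male array and Npas2, chosen after the values were seen, was 1.46-fold higher on the female array. Ribosomal protein genes (-0.02) and respiratory chain genes (-0.03) were inside their ranges, with Rpl39l1 1.89-fold and Cox8b 2.55-fold higher on the female array. Of the 35 lists, 4 lay above and 8 below their ranges; the lists share genes, so these are not independent counts.

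**Figure D3:**
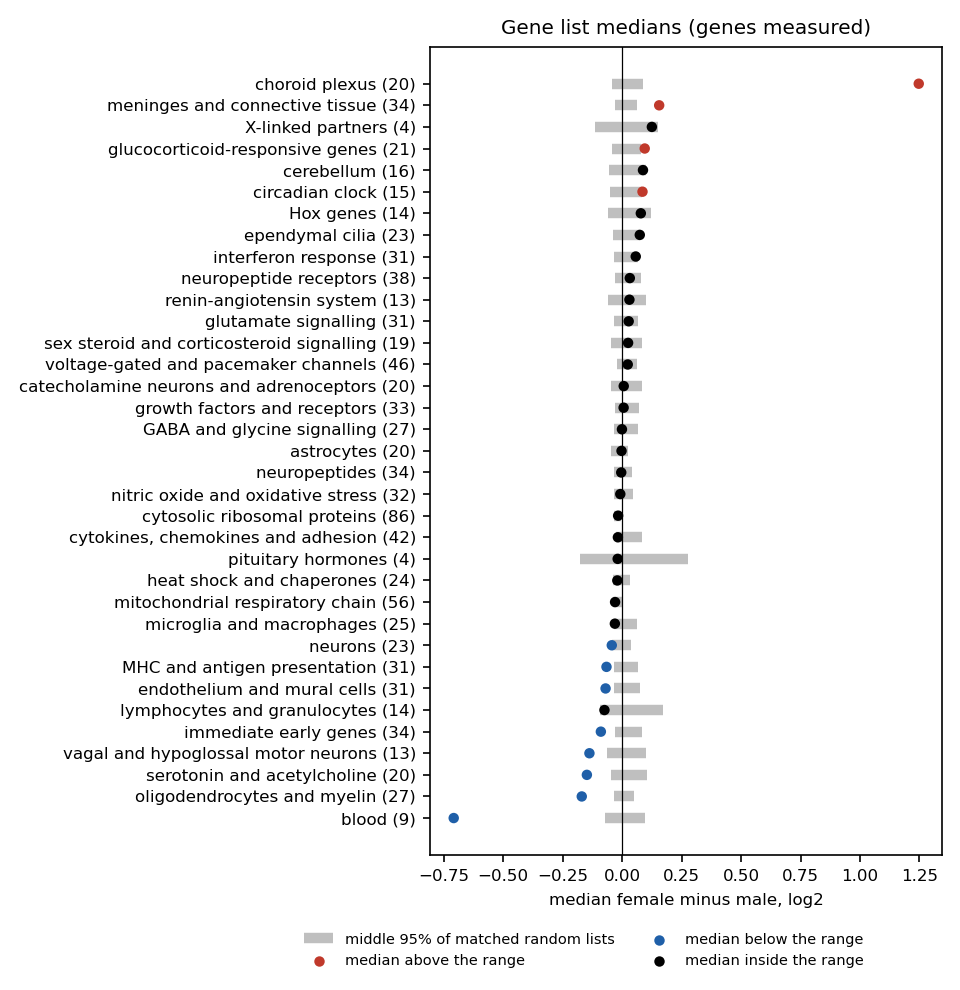
Median female minus male difference (log2) of 35 gene lists, with the number of genes measured in parentheses; grey bars are the middle 95% of matched random lists, and points are red above, blue below and black inside that range. The choroid plexus median of 1.25 and the blood median of -0.71 lie furthest from 0.

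Some genes were above background on 1 array only, 462 on the female and 150 on the male array. A bound of at least 2-fold held for 32 and 24 of them. Among those with a plain symbol, the largest bounds on the female array were at least 17.8-fold for Mfrp, 7.22-fold for Tmem72, 6.46-fold for Vcsa2, 4.76-fold for the lipid transporter gene Abca4 and 4.28-fold for the caveolin gene Cav3. Tmem72 is on the choroid plexus list. On the male array Eif2s3y was followed by Rnase11 at no less than 22.3-fold, Oas1e at 6.41-fold, Asb12 at 5.59-fold and the transcription factor gene Hand2 at 4.82-fold.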

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

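Probes without a gene name were used in no comparison above, and 4 of their values stood out. Of the 16282 such probes measured on both arrays, 52 were at least 2-fold higher on the female array and 27 on the male array. Probe A_44_P597131 had a scaled signal of 322 on the female array and was not well above background on the male array, a bound of at least 882-fold. Probe A_44_P1116620 reached 10.97 on the male array and was not well above background on the female array, a bound of at least 31.9-fold. Without names it could not be told whether these 2 probes read transcripts of the sex chromosomes, such as Xist, which had no named probe. Probe A_44_P1116620 falls by number between probes of the Y-linked genes Tspy1 (A_44_P1116585) and Uty (A_44_P1116631). That order alone does not name its transcript.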

How the results depend on the processing

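Chosen after seeing the data were centring on spike-in controls and the counts without the genes of the fixed choroid plexus and blood lists. The other settings were planned. No paired analysis was possible because each sex has 1 array and no result comes from a test. Among the 58 genes past 1.5-fold that the naming rule picked, all 58 kept their direction in each of the 13 settings where they had a value. Only 24 had a value in the brighter part of the probes, and 22 of these stayed past 1.5-fold under all 13 settings. Of the 58 genes, 24 were in the dimmest 25% of the signal range. Normexp correction took 25 of the 58 below 1.5-fold and no background correction 21, both on each spot's median signal. The counts of genes 2-fold higher on the female and male arrays were 20 and 7 with normexp, 22 and 9 without background correction, 43 and 31 after quantile normalization, and 70 and 13 on spike-in controls. They were 256 and 79 with probes above background on either array, 555 and 217 without a filter and 7 and 8 in the brighter part of the probes, where fewer genes were tested. Counting every probe gave 62 and 31, a 1.5-fold limit 201 and 107, and a 3-fold limit 22 and 6. The authors' table and kept outlier spots gave 54 and 20, and leaving out the genes of the fixed choroid plexus and blood lists gave 41 and 20. No gene of the blood list was past 2-fold. Cltrn and Col8a1, on the second choroid plexus list described below, were past 2-fold and were not left out. The saturation setting moved nothing, since no spot was saturated. Genes above background on the male array only numbered 234 with the positive and significant flag, and those with a bound of 2-fold or more were 32 on the female and 24 on the male array. Centring on spike-in controls placed the median of all genes at 0.11, against 0.02 in the main setting, and moved every list by that same step. It turned the medians of antigen presentation to 0.025, neurons to 0.048, endothelium to 0.022 and immediate early genes to 0.0017. It gave -0.057 for serotonin and acetylcholine, -0.079 for oligodendrocytes, -0.046 for motor neurons, 1.34 for choroid plexus, 0.25 for meninges, -0.62 for blood, 0.19 for glucocorticoid-responsive genes and 0.18 for clock genes. No list's place among random lists can move with that step, and no other setting turned the direction of a list that lay outside its random range. Drawn anew under each of 13 settings, the random range held the clock and neuron medians in 5, the meninges and immediate early medians in the brighter part of the probes only, and none of the 8 other outlying medians. Median centring, spike-in centring, the authors' values and the saturation setting can barely move a place, so they add little to these counts. With normexp the medians were -0.068 for serotonin and acetylcholine, 1.01 for choroid plexus, -0.039 for endothelium, 0.084 for meninges, -0.63 for blood and 0.035 for clock genes. Without background correction they were -0.053 for serotonin and acetylcholine, 1.11 for choroid plexus, -0.035 for endothelium, 0.11 for meninges and -0.63 for blood. Median centring gave -0.10 for antigen presentation, -0.20 for oligodendrocytes, -0.076 for neurons, -0.10 for endothelium, 0.12 for meninges, -0.12 for immediate early genes and 0.063 for glucocorticoid-responsive genes. Loess gave -0.19 for oligodendrocytes, -0.10 for endothelium and 0.10 for meninges, and quantile normalization -0.11 for endothelium and 0.094 for meninges. In the brighter part of the probes the medians were -0.067 for serotonin and acetylcholine, -0.21 for motor neurons, 1.01 for choroid plexus, 0.048 for meninges, -0.038 for immediate early genes, 0.15 for glucocorticoid-responsive genes and 0.15 for clock genes. The brightest probe of a gene gave -0.10 for serotonin and acetylcholine and -0.18 for motor neurons, and counting every probe gave -0.10 for motor neurons and -0.10 for endothelium. Beyond the shift by spike-ins and the number of genes tested, the cause was not tested. The signal over background limits the dim genes: the spot SD was 0.18 in the dimmest 25% of the signal range and 0.04 in the brightest 25%.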

Other observations

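Chosen only after results were seen were centring on spike-in controls, the check of a second list without shared genes and the point on pools of each sex. The other tests below were written before their results were seen, except that the spike-in shift was known when the scaling tests were written.

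The choroid plexus genes were higher on the female array, with a median of 1.25, and Ttr stood at 9325 there against 617. A local flaw is argued against by the 798 spots around the list's 46 spots, whose median difference was 0.0087. Scaling is argued against too, since the median stayed 1.22 or more above that of all genes under every scaling run, of which quantile and loess scaling can move it. Choroid plexus tissue in the female pool may account for the pattern. A second list of 24 measured choroid plexus genes, none of them on a fixed list, had a median of 0.15. Its random lists had -0.04 to 0.09. Measured genes are above background on both arrays by definition, so their signal on the male array was set by the filter. Cltrn was 13.4-fold and Col8a1 2.15-fold higher on the female array, but Slc28a3 1.40-fold and Slc5a11 1.32-fold higher on the male array. The sex of the animals stays open as well and cannot be told apart from dissection with 1 pool of each sex.

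The blood genes were higher on the male array, and scaling is argued against by a median that stayed at -0.70 or lower relative to all genes. More blood in the male pool could account for the globin genes, such as Hba-a1 at 5130 against 3310, but a second erythroid list gave it no support. Its 14 measured genes had a median of 0.012, on the side of 0 written in advance as speaking against the explanation, though well inside the random range of -0.07 to 0.14 and with 8 genes higher on the female and 6 on the male array. More blood thus stays open without a test in its favour, as does a difference between the sexes, which was not tested.

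The motor neuron genes had a median of -0.14, and relative to all genes it stayed at -0.15 or lower under every scaling run. A larger share of motor neuron tissue in the male pool could account for this: a second list of 12 measured genes had a median of -0.14, below its random range of -0.06 to 0.10. However, 5 of the 12, among them the neurofilament genes Nefl, Nefm and Nefh, were also on fixed lists whose medians had been seen. The 7 others had a median of -0.04, inside a random range of -0.12 to 0.17, so the second list decides nothing on its own, and a sex difference remains open and untested.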
